A study of Mus musculus with 20 samples.

How the data were processed

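The deposited data were counts of reads per gene, 1 table for each of 20 libraries from mouse ESCs, in 10 groups of 2 biological replicates. Per the submitters' processing notes, the authors aligned reads with STAR 2.3.0e to mm9 and counted them per gene with HTSeq, whose version is not given in the sources used here. The files held whole numbers for 37991 Ensembl gene IDs together with HTSeq's tallies of reads that were not assigned. Reads outside annotated genes came to 19.8% to 23.7% in total libraries, 4.75% to 12.9% in polysome libraries and 5.26% to 8.12% in the actinomycin D series. A tally of reads aligned to several places was above 0 in the total libraries alone. Symbols, biotypes and positions came from GENCODE M21 on GRCm38 by gene ID. They covered 32919 IDs and at least 98.6% of the counts of each library. Whether RNA was selected by poly(A) is not given in the sources used here.

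Libraries held between 13832829 and 35170012 gene counts. The spread between 2 replicates relative to counting error (chi-square per degree of freedom) ran from 1.27 in KO at 8 h to 70.8 in WT polysomes. Counting error was thus a large part of the spread in some groups of the actinomycin D series and a small part in WT polysomes. Groups, tests, gene lists and the rule for named genes were chosen before the data were examined. Total and polysome libraries (8) were fitted together, as were the 12 libraries of the actinomycin D series. The fits used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood dispersions and F-tests. P values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. The contrasts were KO against WT in total RNA, in polysomes and at 0 h, the difference between the polysome and total contrasts (association), the slope over 0, 4 and 8 h in WT, its difference between KO and WT, and the difference between the KO changes of day 3 and day 2, fitted on 8 libraries. Levels are given as TMM-scaled CPM, which are counts relative to library size, with SD, and log2 changes with the standard error of the fit.

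For each comparison 17 gene lists were tested against all other genes with camera from limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the lists. They covered CCR4-NOT subunits, other deadenylation and decapping factors, pluripotency factors, markers of post-implantation epiblast, primitive endoderm, trophectoderm, mesoderm and neuroectoderm, 2-cell-stage genes, p53 targets, ATF4 and integrated stress response genes, short-lived transcripts, FGF/ERK feedback genes, feeder fibroblast markers, ribosomal proteins, replication-dependent histones and mitochondrially encoded mRNAs. Genes named were the CCR4-NOT subunits, the 6 highest and 6 lowest log2 changes with adjusted p under 0.05, an average log2 CPM of at least 3, non-overlapping groups (in direct comparisons) and an assigned symbol, and for each list with members past the threshold 2 to 4 of the smallest adjusted p. Genes called higher or lower in total RNA were tested as sets in the slope difference, since those libraries are separate.

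The procedure was tested on simulated data with planted changes in 200 genes. With a log2 change of 1, 76% were recovered in the total contrast, 64% in polysomes, 32% in association, 94% at 0 h and 82% in the difference between days, and with a change of 2 the shares were 96%, 89%, 85%, 99% and 95%. Planted slope differences of 0.1 and 0.2 log2 per hour were recovered in 16% and 55%, and slopes in WT in 59% and 93%. False calls made up at most 9.47% of the calls, in the total contrast, which is above the threshold of 0.05. The data themselves called 28.2% of genes in the total contrast, 37% in polysomes and 62.7% at 0 h. These are far larger shares than were planted, so the recovery need not hold for the data.

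Alternatives were RLE scaling, library totals alone, no filter, a filter of 1 CPM, DESeq2 1.42.0, a term for replicate block, a fit of only the 4 libraries compared, each library left out in turn, an estimated correlation in camera, scaling to ribosomal protein or mitochondrial mRNAs, and time as a factor. With 1 library left out, the remaining library of a group was assumed to vary like the other groups. A fit of protein-coding genes alone was added after seeing the data, as were some alternatives for gene lists and sets. Sequence features were taken from GENCODE M21 with Python 3.11.15, and figures were drawn with matplotlib 3.10.9. The 5072 IDs without a symbol were kept in the fits and were not named. HTSeq's tallies of unassigned reads were left out of the fits since they belong to no gene.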

Results

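RNA abundance was measured by RNA sequencing in mouse embryonic stem cells (ESCs) with a conditional allele of Cnot3, a subunit of CCR4-NOT, the complex that shortens poly(A) tails in the cytoplasm. Cells received 0.1 µM 4-hydroxytamoxifen (4OHT) to delete the allele (KO) or DMSO (WT). The 20 libraries formed 10 groups of 2 biological replicates. On day 3 of 4OHT, whole-cell RNA (total) and RNA from polysomes, the fraction of mRNA bound by several ribosomes, were sequenced from both arms. On day 2, actinomycin D, an inhibitor of transcription, was added at 10 µg/ml and RNA was taken at 0, 4 and 8 h. Reads assigned to genes came to between 27664391 and 35170012 per total library, 13832829 and 16688555 per polysome library and 14513891 and 33262905 per library of the actinomycin D series. The 4 WT libraries of the total and polysome experiments carry the source label E14Tg2a, whereas the design names DMSO-treated conditional cells as WT, so the labels leave open whether both arms were of 1 line in these experiments.

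The total libraries stood apart from the other 16. Between 29568 and 32072 genes had at least 1 read, against 19537 to 21086, and 92.0% to 93.5% of gene counts fell in protein-coding genes, against 97.8% to 98.9%. Replication-dependent histones, whose mRNAs end in a stem-loop and lack a poly(A) tail, took 0.666% to 1.18% of counts in total libraries and at most 0.00490% in the others. Rn7sk, a small nuclear RNA made by RNA polymerase III, took 1.59% to 2.297% in total libraries and at most 0.00333% elsewhere. WT polysome replicate 2 also stood apart, with 5.02% of counts in mitochondrially encoded mRNAs, against 0.912% to 1.38% in the other polysome libraries, and the lowest correlation of log2 counts with its replicate (Pearson r = 0.972 across genes, which are not independent replicates).

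Cnot3 (ENSMUSG00000035632; chromosome 7, 3645268 to 3661109, plus strand, GRCm38) was lower in KO at every time and in every fraction. In total RNA it fell from 46.6 ± 0.659 to 7.72 ± 0.562 CPM (counts scaled to library size, SD, n = 2), 16.6% of WT, and in polysomes from 86.8 ± 12.4 to 15.9 ± 0.973 CPM, 18.3% of WT. On day 2 before actinomycin D it fell from 107.9 ± 1.28 to 11.7 ± 0.374 CPM, 10.8% of WT. KO held 9.49% of the WT level after 4 h and 6.42% after 8 h. The log2 change was -2.59 ± 0.16 (SE) in total RNA, -2.45 ± 0.15 in polysomes and -3.21 ± 0.07 at 0 h, with adjusted p of 3.01e-05, 1.78e-05 and 4.47e-32.

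**Figure D1:**
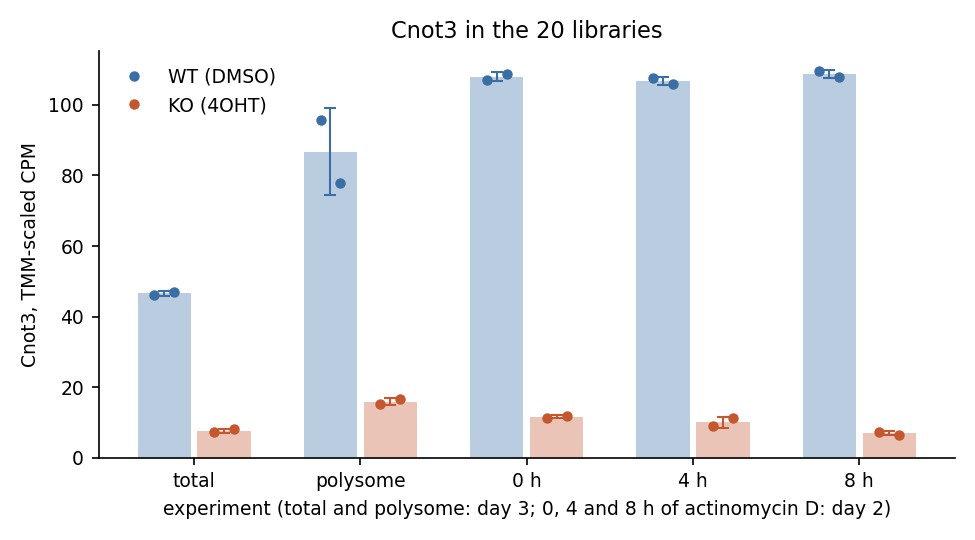
Cnot3 in TMM-scaled CPM in each of the 20 libraries (points), with the mean (bar) and SD (error bar, n = 2) per group. KO means lie between 6.42% and 18.3% of their WT means.

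The first comparison asked which RNAs differed in whole cells on day 3 of deletion. By edgeR, 14 of 17 trophectoderm markers and 11 of 11 genes of the 2-cell embryo rose in KO, while 20 of 26 pluripotency factors, 9 of 11 post-implantation epiblast markers and 43 of 76 ribosomal protein mRNAs (3 under library totals) fell. As sets, these 5 lists passed with the preset correlation and did not with an estimated one (adjusted p from 0.115 to 0.323). The 6 highest changes were in Stmn4, a neuronal stathmin (log2 3.65), Foxj1, which directs the building of motile cilia (3.01), Fgfbp3, a secreted FGF-binding protein (2.83), Slc4a11, a membrane transporter (2.79), Cidea, a lipid droplet protein (2.77), and Hand1, a transcription factor of trophoblast giant cells (2.77). Slc4a11 went from 20.2 ± 0.41 to 139.5 ± 3.46 CPM and Foxj1 from 2.06 ± 0.0698 to 16.6 ± 0.51 CPM (SD, n = 2). Besides Cnot3, the lowest changes were in the zinc finger transcription factors Zic2 (-2.95) and Zic5 (-2.59), the forkhead factor Foxd3 (-2.80), Fut9, a fucosyltransferase that makes the SSEA1 antigen (-2.22), and Enpp3, an ectonucleotidase (-2.16). Zic2 fell from 30.2 ± 2.3 to 3.90 ± 0.282 CPM. Adjusted p ranged from 3.01e-05 for Foxj1 to 0.00111 for Stmn4 in these genes.

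Of 18303 genes tested, 2931 were higher and 2225 lower in KO. A change of at least 1 on the log2 scale was reached by 1747 of the higher and 516 of the lower genes. The split between directions depended on scaling. With library totals alone, which moved the median of all genes to 0.28 from 0.01, 5179 were higher and 908 lower, and DESeq2 called 1939 higher and 2691 lower. Leaving out 1 library also moved the counts: without any 1 of the 4 total libraries 656 to 996 genes were higher and 603 to 1120 lower, and without either WT polysome library, which share the fit, 4511 to 4516 were higher and 5004 to 5011 lower. A fit of the 4 total libraries alone gave 5469 and 5467. The joint fit shares its spread with the WT polysomes, whose replicates differed most. Their chi-square per degree of freedom was 70.8, against 11.2 in WT and 7.27 in KO total libraries. A call lost without 1 total library thus need not mean a smaller change.

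Of 26 pluripotency factors tested in total RNA, 20 fell and 6 did not pass (median log2 -1.02; 21 lower and 1 higher when adjusted over the list alone). As a set they were lower than other genes (camera adjusted p = 3.04e-14, adjusted p = 0.152 with an estimated correlation). Fgf4, a growth factor of the inner cell mass, fell by 1.84 ± 0.17 (SE), Lin28a, which blocks let-7 maturation, by 1.52 ± 0.20, and the 5-methylcytosine oxidases Tet1 and Tet2 by 1.51 ± 0.16 and 1.32 ± 0.18. Pou5f1 and Sox2, which were singled out after their values were seen, had log2 changes of -1.08 and -1.01, and Nanog had -0.45 (adjusted p = 0.112). Post-implantation epiblast markers fell in 9 of 11 (10 when adjusted over the list alone, median -1.32, camera adjusted p = 1.9e-14, adjusted p = 0.115 with an estimated correlation), among them Foxd3, Zic2, Zic5 and the Wnt effector Lef1 (-2.01 ± 0.20). Among FGF/ERK feedback genes, 6 of 8 fell and 1 rose, the same when adjusted over the list alone (median -0.76, camera adjusted p = 0.00359, adjusted p = 0.424 with an estimated correlation). The ERK inhibitor Spry4 fell by 1.83 ± 0.28 and the ETS factor Etv5 by 1.14 ± 0.19, while the ERK phosphatase Dusp4 rose by 1.16 ± 0.21 and did not pass without WT total replicate 1 (adjusted p = 0.0544).

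Trophectoderm markers rose in 14 of 17, with 1 lower and 2 not passing, the same when adjusted over the list alone (median 1.47, camera adjusted p = 3.43e-09, adjusted p = 0.201 with an estimated correlation). Gata2, a trophoblast transcription factor, rose by 2.05 ± 0.24, the keratin Krt19 by 1.84 ± 0.25, and the homeobox factor Esx1 by 1.96 ± 0.28. All 11 of the 2-cell-stage genes rose, and all 11 when adjusted over the list alone (median 1.42, camera adjusted p = 1.24e-14, adjusted p = 0.115 with an estimated correlation). Zscan4c changed by 1.78 ± 0.15, Zscan4d at 1.5 ± 0.15 and Tmem92 at 1.42 ± 0.18. Zscan4 copies are near-identical, so the split of reads among them is uncertain. Mesoderm markers rose in 4 of 10 and fell in 2, also when adjusted over the list alone (median 0.51, camera adjusted p = 0.061, and 0.0414 without KO total replicate 2), led by Wnt3, a ligand of the primitive streak (2.33 ± 0.22), and T, the brachyury factor (2.22 ± 0.36). Of 8 neuroectoderm markers, 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.823; median 0.58 and mean 0.11 with a test direction of lower). The eye and brain factor Pax6 fell by 1.42 ± 0.22 and Sox11 by 1.37 ± 0.26, the latter not passing without KO total replicate 1 (adjusted p = 0.0504). Of 21 primitive endoderm markers, 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.59; median -0.04, mean 0.02, test direction lower): the forkhead factor Foxa2 (1.19 ± 0.24), the endocytic receptor Cubn (-1.09 ± 0.26) and the laminin chain Lamc1 (-1.0 ± 0.24). Foxa2 did not pass without WT replicate 2, KO replicate 1 or KO replicate 2 of the total libraries, Cubn not without WT replicate 1, WT replicate 2 or KO replicate 1, and Lamc1 not without any 1 of the 4 (adjusted p from 0.0536 to 0.0978).

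Among p53 targets, 9 of 18 rose and 2 fell (10 and 2 when adjusted over the list alone, median 0.46, camera adjusted p = 0.00302, adjusted p = 0.152 with an estimated correlation). The kinase Plk2 rose by 1.77 ± 0.14, the desmosomal protein Perp by 1.70 ± 0.21 and Mdm2, the ubiquitin ligase of p53, by 1.2 ± 0.18. Short-lived and immediate early transcripts rose in 11 of 21 and fell in 3 (11 and 4 when adjusted over the list alone, median 0.70, camera adjusted p = 0.000568, adjusted p = 0.201 with an estimated correlation). The anti-proliferative factor Btg2 rose by 1.77 ± 0.15, the BMP targets Id3 and Id2 by 1.54 ± 0.14 and 1.42 ± 0.17, and the stress factor Atf3 by 1.87 ± 0.21. Feeder fibroblast markers rose in 7 of 11, also when adjusted over the list alone (median 0.81, camera adjusted p = 0.00496, adjusted p = 0.201 with an estimated correlation), among them Thy1 (0.81 ± 0.17) and the fibrillin Fbn1 (0.91 ± 0.20). Thy1 did not pass without any 1 of the 4 total libraries (adjusted p from 0.0626 to 0.104), and Fbn1 not without WT total replicate 1 or KO total replicate 2 (adjusted p of 0.15 and 0.142).

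Ribosomal protein mRNAs were lower in 43 of 76 (63 when adjusted over the list alone, median -0.60, camera adjusted p = 8.28e-14, adjusted p = 0.323 with an estimated correlation). With library totals alone the median was -0.34 and 3 were lower. Rpl35 (-0.70 ± 0.14) and Rps25 (-0.78 ± 0.17) had the smallest adjusted p and did not pass without WT total replicate 1 or KO total replicate 2 (adjusted p from 0.0597 to 0.0921). Replication-dependent histones were lower in 41 of 52 and higher in 2 (42 and 2 when adjusted over the list alone, median -0.94, camera adjusted p = 5.96e-15, adjusted p = 0.201 with an estimated correlation), as with Hist1h2ai (-1.08 ± 0.13) and Hist1h2ab (-1.01 ± 0.15). Histone genes share reads with near-identical copies, and their counts came almost wholly from the total libraries, whose share of small nuclear and other noncoding RNA was also the highest. Of 11 mitochondrially encoded mRNAs, 1 fell, mt-Nd3 (-0.99 ± 0.31, not past the threshold when adjusted over the list alone; median -0.62, camera adjusted p = 0.024, adjusted p = 0.531 with an estimated correlation). The call of mt-Nd3 was lost without any 1 of the total libraries (adjusted p from 0.143 to 0.27) and that of the list without WT total replicate 1 (adjusted p = 0.0625).

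In the complex itself, 3 of 11 CCR4-NOT subunits fell, 2 of them when adjusted over the list alone (median -0.22, camera adjusted p = 0.00359, adjusted p = 0.323 with an estimated correlation). The list includes Cnot3, the deleted gene, and was not tested without it. Next to Cnot3, the deadenylase subunits Cnot6 (-0.65 ± 0.16) and Cnot7 (-0.43 ± 0.15) fell, neither of which passed without any 1 of the 4 total libraries (adjusted p from 0.0595 to 0.187). The scaffold Cnot1 was at -0.54 ± 0.21 (adjusted p = 0.075), and it passed as lower, as did Cnot4 and Cnot10, and Cnot2 as higher (0.21), without either WT polysome library (adjusted p from 0.000185 to 0.0332). Of 21 other deadenylation and decapping factors, 4 fell, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.0874), led by the decapping enzyme Dcp2 (-1.09 ± 0.17) and the microRNA effector Tnrc6c (-0.90 ± 0.18). The list passed without KO total replicate 2 (median -0.16) or either WT polysome library (adjusted p from 0.0262 to 0.0311). Of 12 ATF4 and integrated stress response genes, 3 rose (3 higher and 1 lower when adjusted over the list alone, median -0.11, mean 0.16, test direction higher, camera adjusted p = 0.436). The mTORC1 inhibitor Ddit4 rose by 1.54 ± 0.15 and the pseudokinase Trib3 by 0.81 ± 0.20, the latter not passing without any 1 of the total libraries (adjusted p from 0.0854 to 0.151). Under library totals the medians of 4 of these lists turned positive: CCR4-NOT subunits (0.04), the other factors (0.18), ATF4 genes (0.16) and primitive endoderm markers (0.23).

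**Figure D2:**
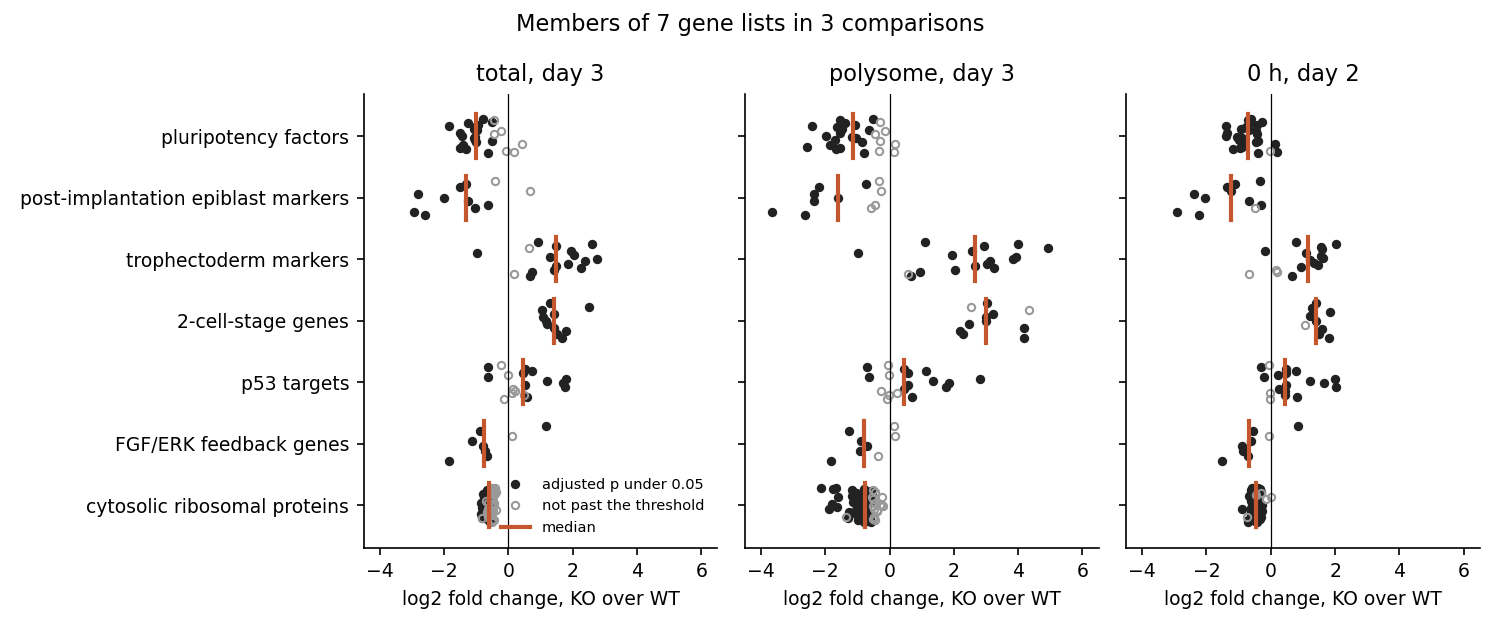
Log2 fold change of KO over WT for the members of 7 gene lists in total RNA, polysomes and at 0 h (filled points: adjusted p under 0.05; bars: list medians). Pluripotency medians are -1.02, -1.13 and -0.69, and trophectoderm medians are 1.47, 2.66 and 1.16.

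The second comparison asked which mRNAs differed in polysomes on day 3. The highest changes were again in Stmn4 (log2 5.0), Cidea (4.32), Hand1 (3.84) and Foxj1 (3.51), joined by Zscan4f and by Rin3, an activator of Rab5 (3.48). Hand1 went from 6.36 ± 2.35 to 91.8 ± 46 CPM (SD, n = 2) and Foxj1 from 2.96 ± 0.401 to 34.0 ± 0.575 CPM. Zscan4f had 0 and 1 reads in the WT polysome libraries and 9 and 16 in KO, too few for a firm ratio. The lowest changes were in A2m, a protease inhibitor (-3.86), Zic2 (-3.67), the matrix protein fibronectin, Fn1 (-3.11), Lefty1, an antagonist of Nodal (-3.05), Mir295, of the microRNA cluster typical of ESCs (-3.04), and Enpp3 (-3.01). Fn1 fell from 699.6 ± 217 to 81.1 ± 10.8 CPM and Lefty1 from 172 ± 61.8 to 20.9 ± 13.9 CPM. Adjusted p ranged from 9.9e-06 for Foxj1 to 0.00214 for Mir295.

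In polysomes 2904 genes were higher and 3859 lower of 18303 tested, 1843 and 1491 of them by at least 1 on the log2 scale. Library totals, under which the median of all genes was 0.15 against -0.08, gave 4547 higher and 2000 lower. The counts were 1636 and 1844 without KO polysome replicate 2, the lower count was 1849 without KO polysome replicate 1, and it was 2412 to 2429 without any 1 of the total libraries. A fit of the 4 polysome libraries alone gave 1860 higher and 1427 lower. Of the genes higher in total RNA, 1958 were higher in polysomes, where independence would give 465, and 1616 were lower in both, where it would give 469.1. Across genes the 2 changes correlated (Pearson r = 0.675, Spearman rho = 0.723; genes are not independent replicates).

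Pluripotency factors fell in 19 of 26, also when adjusted over the list alone (median -1.13, camera adjusted p = 1.4e-13, adjusted p = 0.179 with an estimated correlation). Fgf4 changed by -2.40 ± 0.17, the germ cell and naive state factor Prdm14 at -1.69 ± 0.15, Tet1 at -1.54 ± 0.16 and the maternal factor Dppa3 at -1.54 ± 0.16. Epiblast markers fell in 7 of 11 (8 when adjusted over the list alone, median -1.60, camera adjusted p = 5.9e-09, adjusted p = 0.179 with an estimated correlation), including Foxd3 (-2.35 ± 0.19), Zic5 (-2.62 ± 0.21) and Lef1 (-1.60 ± 0.22). Trophectoderm markers rose in 15 of 17 and fell in 1, also when adjusted over the list alone (median 2.66, camera adjusted p = 6.12e-15, adjusted p = 0.179 with an estimated correlation). Krt19 rose by 3.04 ± 0.26 and the transcription factors Gata3 and Dlx3 by 3.94 ± 0.36 and 2.95 ± 0.28. Of 11 2-cell-stage genes, 9 rose (10 when adjusted over the list alone, median 2.99, camera adjusted p = 1.19e-05, adjusted p = 0.223 with an estimated correlation), among them Tmem92 (3.22 ± 0.37) and Zscan4d (2.29 ± 0.31). Their WT polysome counts were at most 8 reads per library, and 2 members had 0 reads in both; without these the median was 2.99 over 9 members. Mesoderm markers rose in 4 of 10 and fell in 1 (5 and 2 when adjusted over the list alone, median 0.50, camera adjusted p = 0.157). Wnt3 changed by 3.69 ± 0.27 and the ligand Bmp4 at -1.15 ± 0.17. Of 8 neuroectoderm markers, 3 rose and 3 fell (4 and 3 when adjusted over the list alone, median 0.68, camera adjusted p = 0.955). Pax6 changed by -2.25 ± 0.30 and the intermediate filament Nes at 1.13 ± 0.21. Of 21 primitive endoderm markers, 1 rose and 5 fell, also when adjusted over the list alone (median -0.01, camera adjusted p = 0.735), led by Lamc1 (-1.95 ± 0.24) and Cubn (-1.84 ± 0.36). This list passed without WT polysome replicate 1 (median -0.10, adjusted p = 0.0469), and its median turned positive under library totals (0.26) and RLE scaling (0.02).

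Among p53 targets in polysomes, 10 of 18 rose and 2 fell, also when adjusted over the list alone (median 0.45, camera adjusted p = 0.000393, adjusted p = 0.179 with an estimated correlation). Plk2 changed by 1.75 ± 0.14, Perp at 1.86 ± 0.21 and the cyclin Ccng1 at 1.12 ± 0.17. Short-lived transcripts rose in 10 of 21 and fell in 3, also when adjusted over the list alone (median 0.62, camera adjusted p = 1.86e-05, adjusted p = 0.204 with an estimated correlation), led by Id2 (2.83 ± 0.18) and the AP-1 component Fosl1 (5.12 ± 0.36, from 3 and 4 reads in WT). FGF/ERK feedback genes fell in 5 of 8, also when adjusted over the list alone (median -0.80, camera adjusted p = 0.0128, adjusted p = 0.479 with an estimated correlation). The ERK inhibitors Spry4 changed by -1.82 ± 0.28 and Spry1 at -0.92 ± 0.15. Feeder fibroblast markers rose in 5 of 11, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.0255, adjusted p = 0.247 with an estimated correlation). The matrix enzyme Loxl1 changed by 1.22 ± 0.21 and vimentin, Vim, at 0.78 ± 0.16. Neither of the last 2 lists passed without WT polysome replicate 1 (medians of -0.55 and 0.03, adjusted p of 0.171 and 0.0854). Ribosomal protein mRNAs were lower in 58 of 76 (67 when adjusted over the list alone, median -0.76, camera adjusted p = 1.11e-11, adjusted p = 0.454 with an estimated correlation), 26 of them under library totals, and Rpl10 fell by 1.68 ± 0.29 and Rpl13 by 1.18 ± 0.21.

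Mitochondrially encoded mRNAs fell in 8 of 11 (9 when adjusted over the list alone, median -1.95, camera adjusted p = 0.00371, adjusted p = 0.479 with an estimated correlation). They moved with WT polysome replicate 2, which held 5.02% of its counts in them; without it the median was -0.61. The NADH dehydrogenase subunits mt-Nd6 (-1.95 ± 0.39) and mt-Nd5 (-1.74 ± 0.35) did not pass without KO polysome replicate 2 (adjusted p of 0.0572 and 0.0636). CCR4-NOT subunits fell in 3 of 11, also when adjusted over the list alone (median -0.15, camera adjusted p = 0.0721): Cnot3, Cnot6 (-0.79 ± 0.16) and Cnot10 (-0.40 ± 0.13). Here too the list was tested only with the deleted gene in it. Cnot6 was lost without KO polysome replicate 1 (adjusted p = 0.0577) and Cnot10 without any 1 of 6 libraries (adjusted p from 0.122 to 0.196), while the list passed without WT polysome replicate 2 (median -0.28) or KO polysome replicate 2 (adjusted p of 0.00143 and 0.0349). The median of the list was 0.11 under library totals. Without WT polysome replicate 1, Cnot2 (0.50) and Cnot11 (0.37) passed as higher and Cnot7 (-0.45) as lower (adjusted p from 0.00074 to 0.00798). Without replicate 2, Cnot1 (-0.62), Cnot8 (-0.34) and Cnot9 (-0.28) passed as lower (adjusted p from 0.000497 to 0.0387). The other deadenylation and decapping factors fell in 7 of 21, also when adjusted over the list alone (median -0.36, camera adjusted p = 0.0689). Tnrc6c changed by -0.92 ± 0.18 and Pan3, of a second deadenylase, at -0.84 ± 0.17. This list passed without the same libraries (adjusted p of 0.00115 and 0.0227). Of 12 ATF4 genes, 1 rose and 5 fell (1 and 6 when adjusted over the list alone, median -0.51, camera adjusted p = 0.449), and the list passed without WT polysome replicate 2 (adjusted p = 0.00696). Ddit4 rose by 1.37 ± 0.15 and Atf4 fell by 0.88 ± 0.19, not passing without KO polysome replicate 2 (adjusted p = 0.0708). Histones rose in 2 of 52 and fell in 2 (1 higher when adjusted over the list alone, median -0.36, camera adjusted p = 0.923), the linker histone Hist1h1c by 1.53 ± 0.19.

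The third comparison asked whether polysome association, the polysome change minus the total change, differed in KO. It did so for 2 of 18303 genes by edgeR, both named after their values were seen: Hist1h1c, a linker histone (2.31 ± 0.25), and Fgf1, a growth factor (-2.90 ± 0.33), each with adjusted p = 0.0276. At an unadjusted p under 0.05 there were 2304 genes, and DESeq2 called 32 higher and 35 lower. The count depended on the libraries: without WT polysome replicate 1, 1848 genes were higher and 3111 lower, and without replicate 2 the counts were 24 and 47, both genes included in each case. Without any 1 of the other 6 libraries neither gene passed (adjusted p from 0.124 to 0.598), at changes of 2.17 to 2.56 for Hist1h1c and -2.95 to -2.68 for Fgf1. Without WT polysome replicate 1, Cnot1 (0.60) and Cnot11 (0.495) were higher (adjusted p of 0.00698 and 0.0125). Cnot3 itself had a change in association of 0.15 ± 0.21 (adjusted p = 0.811). The total libraries also differed from the polysome libraries in composition, as described above. For single genes and for lists, a difference in association cannot be told apart from an effect of the kind of library.

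As sets, 5 of 17 lists differed in association, none with an estimated correlation. Trophectoderm markers were higher (median 0.76; 5 when adjusted over the list alone, camera adjusted p = 9.61e-08, adjusted p = 0.798 with an estimated correlation), as were 2-cell-stage genes (median 1.81; 6 when adjusted over the list alone, camera adjusted p = 1.52e-05, adjusted p = 0.798 with an estimated correlation), and the median was also 1.81 over the 9 members left without the 2 that had no reads in WT polysomes. Histones, among them Hist1h1c, had a median of 0.32 (2 higher when adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.855 with an estimated correlation), set by counts that came mainly from the total libraries. ATF4 genes were lower (median -0.41; 2 when adjusted over the list alone, camera adjusted p = 0.00707, adjusted p = 0.798 with an estimated correlation). Mitochondrially encoded mRNAs were lower (median -1.32, camera adjusted p = 0.00289, adjusted p = 0.847 with an estimated correlation), and without WT polysome replicate 2 their median was 0.06. Without WT polysome replicate 1, 2-cell-stage genes (median 1.775), ATF4 genes (-0.03) and histones (0.16) did not pass (adjusted p of 0.0676, 0.697 and 0.201), and histones not without WT total replicate 1 (adjusted p = 0.189). The other 12 lists had medians from -0.30 for primitive endoderm markers to 0.25 for feeder markers, with means of -0.10 and -0.11; the signs of median, mean and test also differed for the epiblast, mesoderm and FGF/ERK lists. Without WT polysome replicate 2 the lists of other deadenylation factors (median -0.18), pluripotency factors (-0.28) and p53 targets (0.12) passed. Primitive endoderm markers and FGF/ERK genes also passed, with medians that turned to 0.20 and -0.21 from -0.30 and 0.04 (adjusted p from 2.85e-06 to 0.0394 over the 5 lists). Ribosomal protein mRNAs passed without WT replicate 1 or KO replicate 2 of the total libraries or WT polysome replicate 1 (medians of -0.14, -0.05 and -0.29 from -0.13, adjusted p from 0.00157 to 0.049). Short-lived transcripts passed without KO total replicate 2 or KO polysome replicate 1 (medians of 0.16 and 0.02 from 0.07, adjusted p from 0.00165 to 0.049), as did pluripotency factors without KO polysome replicate 1 (adjusted p = 0.00875).

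The fourth comparison gave the KO change on day 2, before actinomycin D. The highest changes were in the phospholipases Plcd4 (log2 3.04) and Plch2 (2.50), Sytl1, a Rab27 effector (2.62), Slc4a11 (2.51), Trim47, a ubiquitin ligase (2.48), and the kelch protein Klhl26 (2.27). Slc4a11 rose from 28.9 ± 2.42 to 165 ± 5.62 CPM and Klhl26 from 15.3 ± 0.47 to 73.5 ± 3.2 CPM (SD, n = 2). Next to Cnot3, the lowest were Zic2 (-2.93), Zic5 (-2.23), the activin subunit Inhbb (-1.84), the zinc finger repressor Trps1 (-1.83) and the homeobox factor Gbx2 (-1.82). Zic2 fell from 81.0 ± 3.51 to 10.7 ± 1.22 CPM. Adjusted p lay between 4.47e-32 for Slc4a11 and 8.18e-19 for Sytl1.

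Of 15823 genes tested at 0 h, 4718 were higher and 5203 lower, 1591 and 330 of them by at least 1 on the log2 scale. RLE scaling, with the median of all genes at -0.15, gave 3537 higher and 6898 lower, DESeq2 gave 2681 and 5970, and library totals, with the median at 0.14, gave 6619 and 3396. Of 15715 genes tested in both, 2310 were higher at 0 h and in total RNA, where independence would give 781.8, and 1889 were lower in both, where it would give 684.2. Of the 4206 genes called in both, 4199 had the same direction (across genes, Pearson r = 0.834, Spearman rho = 0.86).

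Pluripotency factors at 0 h fell in 23 of 26 and rose in 2, also when adjusted over the list alone (median -0.69, camera adjusted p = 1.29e-18, adjusted p = 0.0195 with an estimated correlation). Lin28a changed by -1.36 ± 0.04, the nuclear receptor Nr0b1 at -1.39 ± 0.05, Fgf4 at -1.40 ± 0.05 and the Nodal co-receptor Tdgf1 at -0.88 ± 0.04. Epiblast markers fell in 10 of 11 (11 when adjusted over the list alone, median -1.24, camera adjusted p = 1.85e-10, adjusted p = 0.0195 with an estimated correlation), including the DNA methyltransferase Dnmt3b (-1.13 ± 0.05) and Foxd3 (-2.39 ± 0.12). FGF/ERK feedback genes fell in 6 of 8 and rose in 1, also when adjusted over the list alone (median -0.67, camera adjusted p = 6.15e-05, adjusted p = 0.0195 with an estimated correlation). Spry4 changed by -1.52 ± 0.05 and the ERK inhibitor Spred1 at -0.89 ± 0.06. Trophectoderm markers rose in 12 of 16 and fell in 1 (13 and 1 when adjusted over the list alone, median 1.16, camera adjusted p = 3.51e-06, adjusted p = 0.0207 with an estimated correlation), with Tfap2c, a trophoblast factor, at 0.67 ± 0.05 and the keratins Krt7 and Krt18 at 1.47 ± 0.12 and 1.22 ± 0.09. The p53 targets rose in 13 of 18 and fell in 2, also when adjusted over the list alone (median 0.45, camera adjusted p = 6.45e-08, adjusted p = 0.0147 with an estimated correlation). Plk2 changed by 2.02 ± 0.06 and Mdm2 at 1.23 ± 0.04. CCR4-NOT subunits fell in 8 of 11 and rose in 1, also when adjusted over the list alone (median -0.29, camera adjusted p = 0.000365, adjusted p = 0.0207 with an estimated correlation). The list includes Cnot3, whose fall was set by the deletion and adds to the result of the set, and it was not tested without Cnot3. The scaffold Cnot1 fell by 0.63 ± 0.04, Cnot6 by 0.67 ± 0.05 and Cnot7 by 0.43 ± 0.05, and Cnot2 rose by 0.28 ± 0.05. Cnot11 (-0.13 ± 0.06) did not pass without KO replicate 1 or WT replicate 2 of 0 h (-0.06 without the latter, adjusted p of 0.165 and 0.426) and was at 0.02 under library totals.

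The 2-cell-stage genes rose in 8 of 9 at 0 h (9 when adjusted over the list alone, median 1.42, camera adjusted p = 0.0111, adjusted p = 0.167 with an estimated correlation). Zscan4d changed by 1.49 ± 0.22 and the deubiquitinase Usp17la at 1.83 ± 0.34, from at most 40 reads per WT library. Short-lived transcripts rose in 11 of 21 and fell in 7, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.0236, adjusted p = 0.0828 with an estimated correlation): Btg2 rose by 1.80 ± 0.05 and Id2 by 1.74 ± 0.08, and the zinc finger factor Egr1 fell by 1.26 ± 0.06. This list did not pass without KO replicate 2 of 0 h (median 0.46) or KO replicate 1 of 4 h (adjusted p of 0.0646 and 0.0763). Ribosomal protein mRNAs were lower in 71 of 76 (72 when adjusted over the list alone, median -0.47, camera adjusted p = 2.85e-15, adjusted p = 0.0519 with an estimated correlation), as with Rpl22 (-0.57 ± 0.04) and Rpl23 (-0.54 ± 0.04). ATF4 genes fell in 8 of 11 and rose in 1, also when adjusted over the list alone (median -0.50, camera adjusted p = 0.00553, adjusted p = 0.167 with an estimated correlation). The serine synthesis enzyme Psat1 changed by -0.63 ± 0.04 and Atf4 at -0.76 ± 0.05. The other deadenylation and decapping factors fell in 10 of 20 and rose in 3, also when adjusted over the list alone (median -0.16, camera adjusted p = 0.00836, adjusted p = 0.201 with an estimated correlation). Dcp2 changed by -0.95 ± 0.04 and the helicase Ddx6 at -0.72 ± 0.04. Feeder markers rose in 5 of 9, also when adjusted over the list alone (median 0.54, camera adjusted p = 0.029, adjusted p = 0.0994 with an estimated correlation). The collagen Col1a1 changed by 1.47 ± 0.15. Primitive endoderm markers rose in 5 of 20 and fell in 2 (4 and 2 when adjusted over the list alone, median 0.30, camera adjusted p = 0.632). Lamc1 changed by -0.88 ± 0.04 and the nuclear receptor Hnf4a at 0.54 ± 0.10. Under RLE scaling 3 of them were higher and 5 lower, and the neuroectoderm and histone medians turned negative. Mesoderm markers rose in 4 of 8 and fell in 2, and neuroectoderm markers rose in 3 of 6 and fell in 2, both also when adjusted over the list alone (camera adjusted p of 0.373 and 0.959; neuroectoderm median 0.10, mean -0.40, test direction higher). Wnt3 changed by 3.22 ± 0.25 and Nes at 0.65 ± 0.06. Of 19 histones 1 rose and 4 fell (1 lower when adjusted over the list alone, median 0.02, mean -0.03, camera adjusted p = 0.959). Of 7 mitochondrially encoded mRNAs 1 fell, mt-Nd1 (-0.59 ± 0.18, not past the threshold when adjusted over the list alone; median -0.44, camera adjusted p = 0.394), which did not pass without either WT library of 0 h (adjusted p of 0.0807 and 0.0869), and the list passed without KO replicate 2 of 0 h (median -0.73, adjusted p = 0.00887).

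The actinomycin D series followed RNA levels after a block of transcription. Whether RNA was selected by poly(A) is not given, and CCR4-NOT shortens poly(A) tails. A slope may therefore also hold changes in tail length, which cannot be told apart here from loss of RNA. Counts were scaled within the series and the labels name no spike-in, so a slope states how a transcript changed relative to the typical transcript, in log2 units per hour, and is not a half-life. In WT, 6142 of 15823 genes were lost faster and 5543 slower than the typical transcript. All 21 short-lived transcripts were lost faster, and all 21 when adjusted over the list alone (median slope -0.39, camera adjusted p = 0.00211, adjusted p = 0.574 with an estimated correlation). So were 15 of 18 p53 targets, with 1 slower, also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0019, adjusted p = 0.229 with an estimated correlation). Ribosomal protein mRNAs were lost slower in 67 of 76 and faster in 3, also when adjusted over the list alone (median 0.14, camera adjusted p = 2.97e-19, adjusted p = 0.113 with an estimated correlation), and histones slower in 15 of 19 (16 when adjusted over the list alone, median 0.17, camera adjusted p = 0.0152, adjusted p = 0.113 with an estimated correlation). Histones took only 0.00168% to 0.00293% of counts in this series, against 0.666% to 1.18% in total libraries. Their slopes thus rest on few reads and may not stand for histone mRNA as a whole. Of 20 primitive endoderm markers 11 were lost slower and 8 faster, also when adjusted over the list alone (median 0.12, mean -0.05, test direction higher, camera adjusted p = 0.0407, adjusted p = 0.505 with an estimated correlation). Scaling to library totals gave 7680 genes lost faster and 3742 slower. Scaling to ribosomal protein mRNAs, which moved the median of all genes to -0.15, gave 12698 and 245 and turned the median of the primitive endoderm list to -0.03 and, by construction, that of the ribosomal list to -0.01.

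The fifth comparison asked whether loss after actinomycin D differed in KO. The highest differences were in transcripts lost quickly in WT and less quickly in KO. Cdt1, which licenses DNA replication, fell in WT from 195 ± 3.56 to 14 ± 0.592 CPM in 8 h and in KO from 217.7 ± 6.99 to 110.8 ± 4.48 CPM (SD, n = 2), a slope difference of 0.36 ± 0.05 log2 per hour. Nufip1, which assists assembly of small nucleolar RNPs, fell from 95 ± 2.09 to 12.6 ± 0.767 CPM in WT and from 120.9 ± 1.28 to 93.4 ± 4.9 CPM in KO (difference 0.32 ± 0.01). Snapc2, of a complex needed for transcription of small nuclear RNA genes (0.36 ± 0.03), the grainyhead factor Grhl3 (0.34 ± 0.04), the kinase Stk17b (0.33 ± 0.08) and Ddx20, a helicase of the SMN complex (0.31 ± 0.02), completed the 6 highest. The lowest were Icosl, a T cell costimulatory ligand (-0.20 ± 0.02), mt-Nd6 (-0.20 ± 0.04), D17Wsu92e (-0.19 ± 0.01), the basement membrane collagen Col4a2 (-0.17 ± 0.02), Cubn (-0.17 ± 0.04) and the postsynaptic scaffold Shank3 (-0.16 ± 0.02). Icosl went from 22.3 ± 1.44 to 62.7 ± 1.69 CPM in WT and from 13.2 ± 0.0879 to 12.6 ± 0.121 CPM in KO. Adjusted p ranged from 4.23e-08 for Nufip1 to 0.0186 for Cubn. Stk17b did not pass without KO replicate 1, WT replicate 1 or WT replicate 2 of 0 h or either KO library of 8 h, Cubn not without KO replicate 1 or WT replicate 2 of 0 h or KO replicate 1, WT replicate 1 or WT replicate 2 of 8 h, and mt-Nd6 not without either WT library of 0 h (adjusted p from 0.0517 to 0.0696).

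**Figure D3:**
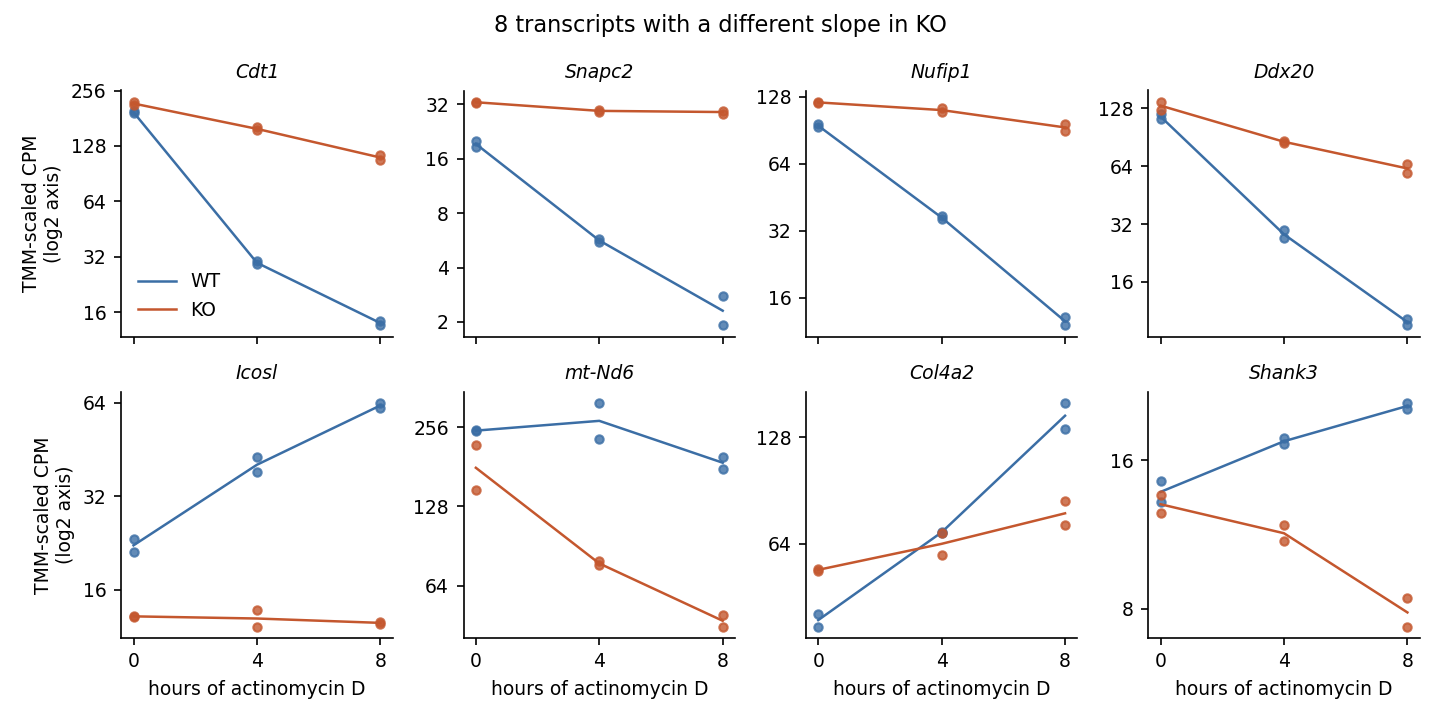
TMM-scaled CPM (log2 axis) of 8 transcripts at 0, 4 and 8 h of actinomycin D (points: libraries, n = 2 per group; lines: means). The upper 4 fell more steeply in WT than in KO, with slope differences from 0.31 for Ddx20 to 0.36 for Cdt1, and the lower 4 had differences from -0.20 for Icosl to -0.16 for Shank3.

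Of 15823 genes, 1614 had a higher and 1389 a lower slope in KO. These calls followed the WT slope: of 6142 genes lost faster in WT, 1453 had a higher and 104 a lower slope in KO, and of 5543 lost slower in WT, 16 had a higher and 1140 a lower slope. The 2 statements share the WT libraries and are not independent. A slope is a straight line over the 3 times. Its fit had a common coefficient of variation between libraries of 0.121, against 0.0358 with time as a factor. Its standard errors and p values thus also hold departures from a straight line. With time as a factor 6714 genes differed at 8 h and 4198 at 4 h. The split of slope calls depended on scaling, with 1693 higher and 556 lower under RLE, 2349 and 648 under library totals, 1860 and 816 with DESeq2, 3691 and 252 under ribosomal protein scaling and 1846 and 9 under mitochondrial mRNA scaling. The lower count was also 560 to 845 without any 1 of WT replicates 1 and 2 or KO replicate 1 of 0 h, KO replicates 1 and 2 or WT replicate 1 of 8 h.

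**Figure D4:**
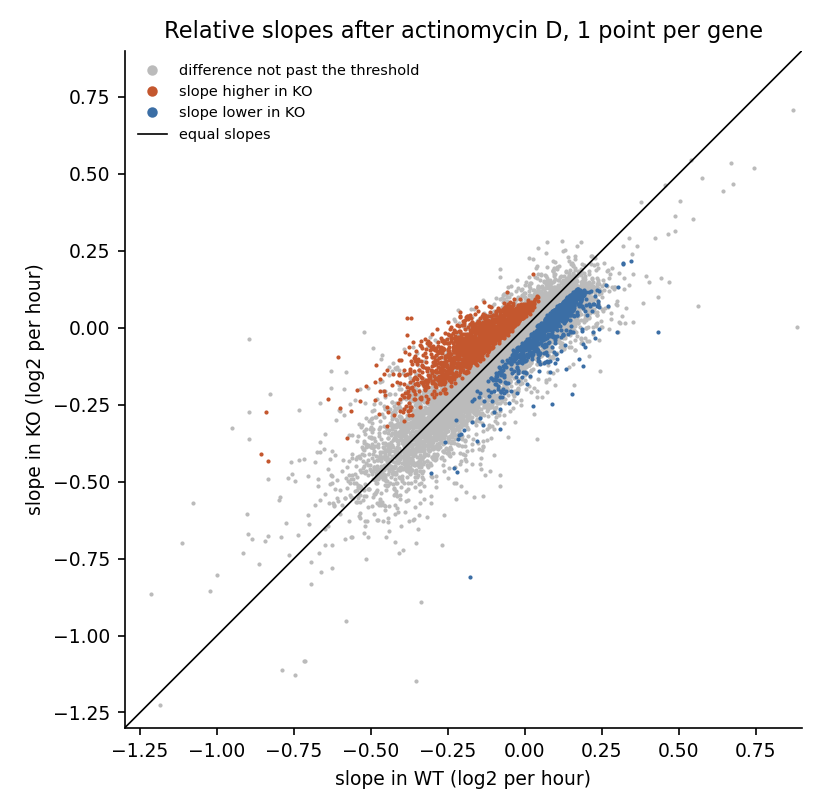
Slope in KO against slope in WT for 15823 genes (log2 per hour, relative to the typical transcript; 8 genes lie outside the axes), with the line of equal slopes. Genes with a higher slope in KO (1614) lie mostly at negative WT slopes and genes with a lower slope (1389) mostly at positive WT slopes.

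Among gene lists, ribosomal protein mRNAs had lower slopes in KO in 22 of 76 and a higher slope in 1 (28 and 1 when adjusted over the list alone, median -0.04, camera adjusted p = 4.14e-06, adjusted p = 0.441 with an estimated correlation), led by Rplp2, of the ribosomal stalk (-0.07 ± 0.01), and Rps21, of the small subunit (-0.08 ± 0.02). Under ribosomal protein scaling 9 were higher and 4 lower, and under mitochondrial mRNA scaling the median was 0.02. Primitive endoderm markers had lower slopes in 9 of 20 and higher in 1 (11 and 1 when adjusted over the list alone, median -0.08, camera adjusted p = 5.13e-06, adjusted p = 0.179 with an estimated correlation), among them the collagens Col4a1 (-0.15 ± 0.02) and Col4a2, and the laminin chains Lama1 (-0.10 ± 0.01) and Lamb1 (-0.08 ± 0.01). Mitochondrially encoded mRNAs had lower slopes in 3 of 7 (4 when adjusted over the list alone, median -0.15, camera adjusted p = 0.00428, adjusted p = 0.441 with an estimated correlation). Pluripotency factors had higher slopes in 7 of 26 and lower in 3 (8 and 5 when adjusted over the list alone, median 0.02, camera adjusted p = 0.0444, adjusted p = 0.179 with an estimated correlation). Utf1, a chromatin factor of ESCs, went from 432.8 ± 0.0343 to 162 ± 5.42 CPM in WT and from 494.7 ± 42.1 to 623.5 ± 18.4 CPM in KO (difference 0.22 ± 0.02), and Nanog, the homeobox factor, had a difference of 0.09 ± 0.01. The pluripotency list did not pass without WT replicate 1 of 0 h (median 0.005), KO replicate 1 of 8 h (0.011) or WT replicate 2 of 8 h (adjusted p of 0.068, 0.0518 and 0.0541).

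In the CCR4-NOT list, Cnot2 (0.15 ± 0.02), Cnot8 (0.06 ± 0.01) and Cnot11 (0.08 ± 0.02) had higher slopes and Cnot3 a lower one (-0.09 ± 0.02); Cnot6 was at -0.04 ± 0.01 and passed without either WT library of 4 h (adjusted p of 0.0466 and 0.0314). The list had 3 higher and 3 lower members when adjusted over the list alone (median -0.01, mean just over 0, camera adjusted p = 0.703). Of 20 other deadenylation and decapping factors 1 had a higher and 4 a lower slope (1 and 6 when adjusted over the list alone, camera adjusted p = 0.475), the decapping cofactor Edc3 at 0.15 ± 0.01 and Dcp2 at -0.11 ± 0.02. Short-lived transcripts had higher slopes in 3 of 21 (2 when adjusted over the list alone, median 0.00, camera adjusted p = 0.476): Id2 (0.31 ± 0.08), Btg2 (0.13 ± 0.03) and Id1 (0.22 ± 0.07), of which Btg2 did not pass without either WT library of 0 h or either KO library of 8 h, Id2 not without any 1 library of 0 h or either KO library of 8 h, and Id1 not without any 1 library but WT replicate 2 of 4 h (adjusted p from 0.0505 to 0.135). Among p53 targets 2 were higher and 2 lower, also when adjusted over the list alone (median just under 0 and mean 0.02, test direction higher, camera adjusted p = 0.489). Ccng1 changed by 0.10 ± 0.01 and Trp53inp1 at 0.09 ± 0.02. The medians of CCR4-NOT subunits (0.02) and other deadenylation factors (0.01) were positive under ribosomal protein scaling, and that of p53 targets under RLE (0.01), library totals (0.02) and ribosomal protein scaling (0.04). Under mitochondrial mRNA scaling the medians of CCR4-NOT subunits (0.04), other deadenylation factors (0.03), ATF4 genes (0.01), p53 targets (0.05) and mesoderm markers (0.02) were positive. Trophectoderm markers were higher in 2 of 16, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.441). Ascl2 changed by 0.25 ± 0.03. Epiblast markers had 1 higher and 2 lower of 11 (camera adjusted p = 0.865), ATF4 genes 3 lower of 11 (camera adjusted p = 0.353), mesoderm markers 2 higher of 8 (median -0.04, mean 0.03, camera adjusted p = 0.856) and feeder markers 1 higher and 1 lower of 9 (camera adjusted p = 0.319; 1 and 3 when adjusted over the list alone). The 2-cell-stage, histone, neuroectoderm and FGF/ERK lists had no member past the threshold by edgeR and medians of -0.09, -0.10, 0.01 and -0.07 (camera adjusted p of 0.106, 0.101, 0.865 and 0.837), the neuroectoderm test having the direction lower. The 2-cell-stage list passed without WT replicate 2 of 0 h or KO replicate 2 of 8 h, and histones without KO replicate 1 or WT replicate 2 of 0 h or KO replicate 1 or WT replicate 1 of 8 h (adjusted p from 0.0253 to 0.0477).

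Whether genes that changed in steady state on day 3 also differed in loss was tested with the total libraries, which are separate from the actinomycin D series. The 2069 genes lower in total RNA had lower slopes in KO as a set (median -0.03, camera adjusted p = 0.00104, adjusted p = 0.067 with an estimated correlation), 326 of them called lower in both, where independence would give 182.9. The 2610 genes higher in total RNA had a median of 0.00 (adjusted p = 0.183), with 270 called higher in both, where independence would give 268.1, and 106 with a lower slope, where it would give 230.7. Of these genes 47.7% had a positive slope difference, against 40.9% of other genes. The median of the set of lower genes turned positive under ribosomal protein scaling (0.01, adjusted p = 0.00787) and mitochondrial mRNA scaling (0.03, adjusted p = 0.0594), within a range of adjusted p from 0.00011 to 0.067 over its alternatives. These scalings also moved the median of all genes, to 0.0256 and 0.0447. The set thus stayed below the median of all genes in both, and its direction against other genes did not turn.

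The last comparison tested whether the KO change in whole-cell RNA differed between day 3 and day 2, experiments whose libraries also differed in composition as described for the total libraries. The total WT libraries also carry the source label E14Tg2a, which the WT libraries of 0 h do not. Day, composition and source label cannot be told apart in this contrast. Of 19071 genes, 485 had a higher and 436 a lower KO change on day 3. ATF4 genes stood out among lists, with 9 of 12 higher on day 3, also when adjusted over the list alone (median 0.50, camera adjusted p = 7.92e-17, adjusted p = 0.0248 with an estimated correlation). RLE gave 341 higher and 651 lower genes, library totals 1049 and 270, DESeq2 163 and 346, and a fit of protein-coding genes 413 and 604. The lower count was 973 and 1327 without WT total replicates 1 and 2 and 267 and 213 without WT replicates 1 and 2 of 0 h. The higher count was 238 without WT total replicate 1 and 221 to 281 without any 1 library of 0 h.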

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

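The tests of the ATF4 pattern, the sorting of label splits by which libraries were exchanged, the ratios with each library left out and the test of WT polysome replicate 2 as the whole cause were chosen only after the result was seen, and the other tests after the patterns but before their own values.

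The KO change differed between day 3 total RNA and day 2 by a test of the difference itself in 921 genes, 485 higher and 436 lower on day 3. Among named genes this held for 20 of 118, with 13 higher and 7 lower. Lineage genes lay on both sides. The trophectoderm genes Hand1 (1.19), Krt18 (1.195), Gata2 (0.98) and Krt19 (0.54), the BMP target Id3 (0.82) and the transporter Slc4a11 (0.31) had a higher KO change on day 3, as had the ATF4 genes Vldlr (1.22), Asns (0.82), Trib3 (0.74), Atf4 (0.61), Psat1 (0.40) and Ppp1r15a (0.33). Cnot3 itself was higher by 0.66. Lower on day 3 were Amn (-0.98), Enpp3 (-0.96), Fut9 (-0.55), Tdgf1 (-0.52), Tet1 (-0.51), Etv5 (-0.47) and Fgf4 (-0.41).

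Of 17 lists, 8 differed between the days: trophectoderm markers (median difference 0.54, adjusted p = 3.1e-06), ATF4 genes (0.50, adjusted p = 7.92e-17), short-lived transcripts (0.14, adjusted p = 0.00177), pluripotency factors (-0.12, adjusted p = 3.28e-06), primitive endoderm markers (-0.21, adjusted p = 0.00218), p53 targets (-0.0748, adjusted p = 0.0296), ribosomal protein mRNAs (-0.13, adjusted p = 0.00676) and histones (-0.85, adjusted p = 0.00671). With an estimated correlation the ATF4 list was past the threshold (adjusted p = 0.0248), and the adjusted p of the others was 0.0964, 0.169, 0.252, 0.461, 0.24, 0.754 and 0.754 in the same order. Ribosomal protein mRNAs did not pass without WT total replicate 1 or KO total replicate 2 (medians of -0.07 and -0.03, adjusted p of 0.913 and 0.589), p53 targets not without KO total replicate 2 or KO replicate 2 of 0 h (adjusted p of 0.0592 and 0.0578), and histones not without WT total replicate 1, WT total replicate 2 or KO replicate 2 of 0 h (medians of -0.71, -1.07 and -0.48, adjusted p of 0.704, 0.141 and 0.12). Epiblast markers passed without WT total replicate 1 (median -0.325, from -0.16), KO total replicate 2 (-0.25), KO replicate 1 of 0 h or WT replicate 2 of 0 h (adjusted p from 0.00554 to 0.0466), mitochondrially encoded mRNAs without KO replicate 1 of 0 h (-0.55, from -0.30, adjusted p = 6.47e-06) and other deadenylation factors without KO total replicate 1 (0.13, from 0.06, adjusted p = 0.0199). Mesoderm, neuroectoderm, 2-cell-stage and FGF/ERK lists had median, mean and test of differing sign.

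ATF4 genes had a median log2 change of -0.02 in total RNA, -0.56 in polysomes and -0.50 at 0 h over 11 members. Polysome and total RNA were of the same day, and the polysome median minus that of 0 h was -0.0646 and minus that of total RNA -0.541 (from -0.346 to -0.549 with any 1 of 12 libraries left out), nearer to 0 h in each case. Members taken singly depended on the libraries: 11 of 11 were nearer to 0 h, but 4 without WT polysome replicate 1 and 5 without WT total replicate 2. By the medians this goes with the preparation of the total libraries as a candidate explanation and, by the rule written for it, argues against time since deletion. That rule takes polysomes to follow total RNA, so a lower association (median -0.41, adjusted p = 0.00707, adjusted p = 0.798 with an estimated correlation, and -0.03 with adjusted p = 0.697 without WT polysome replicate 1), computed from the same libraries, may be an alternative.

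As a set, the 6142 transcripts lost faster in WT were lost less fast in KO (median slope -0.183 in WT and -0.148 in KO). Singly, 1453 of them had a higher and 104 a lower slope past the threshold. The short-lived list did not share this in the slope over 8 h: all 21 were lost faster in WT, but the median difference was 6.13e-05, with 3 higher. Over the first 4 h, with time as a factor, the change was higher in KO in 10 of 21 and lower in 1. The median was then 0.51 (camera adjusted p = 6.01e-05, adjusted p = 0.0497 with an estimated correlation). From 0 to 8 h 6 were higher and 7 lower. Noise shared by both axes would give a slope of KO on WT of 1 once corrected for the reliability of the WT slopes, and the highest of 8 replicate choices gave 0.824. Low counts at late times would leave abundant transcripts at 1, and the highest value in the 3956 genes of highest average count was 0.689, and these values argue against both as the whole cause. A factor per library moves all slopes of an arm alike and by arithmetic cannot bring the slope of KO on WT below 1, so the move of 0.0052 under other scalings was fixed beforehand and is no evidence from the data. The range of slopes was narrower in KO (SD of 0.1338 against 0.1496 in WT, Pearson r = 0.889 across genes, which are not independent replicates), and a change in the order of transcripts was not tested.

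Exchanging the WT and KO labels within time points in 100 of 108 possible splits gave at least 3003 genes with a different slope in 7, the real one included, with 8560 as the highest other, so chance could not be excluded by this count. The 6 other splits exchanged the arms whole at 0 or 8 h, which puts the difference between arms into the slope, so these counts point to a structure of the samples. Of the 99 other splits 12 called any gene, and the 28 that mixed the arms at every time called 0. EdgeR was the only tool run on splits. The real split had 5042 genes at an unadjusted p under 0.05 and these 28 had 15 to 33. Of 15823 genes, 15 to 33 are far below a share of 0.05. Mixing puts the difference between arms into the spread within groups. Few calls were thus fixed beforehand, and these 28 splits do not measure chance.

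The KO change in polysomes over that in total RNA had a median ratio of 1.09 over 9904 genes called at 0 h (0.981 in the 4707 higher and 1.17 in the 5197 lower at 0 h), and a ratio weighted by the change at 0 h of 1.29 (1.24 and 1.41). The median depended on single libraries, at 0.983 without WT total replicate 2 and 1.05 without WT polysome replicate 1, and without any 1 total library it was 1.18 to 1.24 in genes higher and 0.82 to 0.89 in genes lower at 0 h, while the weighted ratio over these genes was 1.26 to 1.43 with any 1 of the 8 libraries left out. Background reads in the total libraries would bring the ratio near 1 at high expression, and it was 1.03 (weighted 1.14) in the 2476 genes of highest and 1.17 (weighted 1.38) in the 2476 of lowest expression; neither pair met the bounds set for either outcome, so a background effect and a difference between fractions cannot be told apart. For WT polysome replicate 2 the bound set beforehand was already met with all libraries and decides nothing. Without it the median ratio rose to 1.12 and the weighted one to 1.43, and the excess of 0.12 of the median over 1 was just above the largest move without another library (0.107), which argues narrowly against it as the whole cause.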

How the results depend on the processing

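The protein-coding fit and some alternatives for lists and sets were chosen after seeing the data. Of 390 values of counts and sets under alternatives, 301 kept within the tolerance and side of the threshold, as did 1541 of 1666 values of gene lists and 5167 of 5580 of named genes. Among lists 72 lost and 52 gained the threshold, and among named genes 362 lost and 44 gained it. The cause of the changes was not tested unless stated.

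With an estimated correlation 0 lists passed in the total, polysome, association and slope contrasts, 6 at 0 h and 1 between days, from 12, 10, 5, 4, 12 and 8; these zeros come from camera, and the preset and estimated versions are the only list tests run. Library totals alone gave 5179 higher and 908 lower genes in total RNA, 4547 and 2000 in polysomes, 3396 lower at 0 h, 648 lower slopes, and 1049 higher and 270 lower between days. RLE gave 556 lower slopes. DESeq2 gave 1939 higher genes in total RNA, 32 and 35 in association, 2681 higher at 0 h, 816 lower slopes and 163 higher between days. No filter gave 34 and 6 in association and 1243 lower between days. Only the 4 libraries compared gave 5469 and 5467 in total RNA and 1860 and 1427 in polysomes. Ribosomal protein scaling gave 3691 and 252 slope differences and 245 and 12698 WT slopes relative to these mRNAs, which in WT were lost slower than the typical transcript and had lower slopes in KO (median -0.0404). Mitochondrial mRNA scaling gave 9 lower slopes. Time as a factor gave 2876 and 3838 genes at 8 h. Genes lower in total RNA had a median slope difference of -0.0285 with adjusted p = 0.067 under an estimated correlation and of 0.0291 with adjusted p = 0.0594 under mitochondrial mRNA scaling, in a range from 0.00011 to 0.067. Under mitochondrial mRNA scaling the median of all genes was 0.0447, still above that of this set.

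Directions turned, among others, for Cnot11 at 0 h under library totals (0.019), for the slopes of Dnmt3a (0.004), Dnmt3b (0.002), Bax (0.012), Psat1 (0.002) and Asns (0.012) under mitochondrial mRNA scaling, for Cnot4 with the 4 h difference (0.688), and for mitochondrially encoded mRNAs in association without WT polysome replicate 2 (0.064, in a range from -1.971 to 0.064 over left-out libraries). Without the same library the medians of primitive endoderm markers (0.20) and FGF/ERK genes (-0.21), not past the threshold with all libraries, also turned in association. Medians of some lists turned positive under library totals where the test against other genes kept its side, such as CCR4-NOT subunits in total RNA (0.04).

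With each library left out in turn, total RNA gave 656 to 4516 higher and 603 to 5011 lower genes and 11 to 14 lists. Polysomes gave 1636 to 4075 and 1844 to 5331 and 9 to 13 lists. Association gave 0 to 1848 and 0 to 3111 by edgeR, against 2304 at unadjusted p under 0.05 and 32 and 35 by DESeq2 with all libraries, and 3 to 9 lists. At 0 h there were 3917 to 4830 and 4574 to 5411 genes and 11 to 12 lists. Slope differences numbered 1179 to 1866 and 560 to 1814, with 3 to 6 lists. Between days there were 221 to 441 and 213 to 1327 genes and 6 to 10 lists. The set of genes lower in total RNA ranged from -0.0310 to -0.0220.

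A term for replicate block, which treats equal replicate numbers as paired, gave 3008 and 2437 genes in total RNA, 2989 and 4025 in polysomes, 1447 and 1157 slope differences. Residuals of same-numbered libraries correlated from -0.0331 to 0.28 in 6 pairs of total and polysome groups and from -0.17 to 0.0793 in 15 pairs of the actinomycin D series. Depth limits genes of few reads, such as 2-cell-stage genes in polysomes, and 2 replicates limit every test.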

Other observations

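Of the tests in this part, those of noncoding RNAs were chosen only after the result was seen. With time as a factor, the change from 0 to 4 h was higher in KO in 14 of 26 pluripotency factors and lower in 3 (16 and 5 when adjusted over the list alone, median 0.31, camera adjusted p = 1.23e-08, adjusted p = 0.167 with an estimated correlation), and to 8 h it was higher in 10 of 26 and lower in 8 (11 and 8 when adjusted over the list alone, median 0.12, camera adjusted p = 0.016, adjusted p = 0.57 with an estimated correlation). Short-lived transcripts were higher at 4 h in 10 of 21 and lower in 1 (11 and 1 when adjusted over the list alone, median 0.51, camera adjusted p = 6.01e-05, adjusted p = 0.0497 with an estimated correlation), and at 8 h 6 were higher and 7 lower, also when adjusted over the list alone (median -0.05, mean 0.07, test direction higher, camera adjusted p = 0.553). The difference between the times was not tested.

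Several noncoding RNAs, chosen after their values were seen, rose relative to the typical transcript after actinomycin D in WT. Rn7sk, made by RNA polymerase III, had a slope of 0.75 ± 0.08 log2 per hour, Rpph1, the RNA of RNase P, 0.50 ± 0.09, and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 0.58 ± 0.09 and 0.34 ± 0.02. In KO the slopes were 0.52, 0.41, 0.49 and 0.29, and the adjusted p of the difference was 0.228, 0.707, 0.679 and 0.187. At 0 h Rn7sk had 11 to 12 reads per WT library and 5 to 25 per KO library, and Rpph1 had 33 to 39 and 19 to 20. In the total WT libraries they had at least 505683 and 237751 reads. The slopes of Rn7sk and Rpph1 thus start from traces in this series. Hprt, which is deleted in part in the E14Tg2a line, had between 3793 and 11115 reads in each of the 20 libraries, 4830 to 5661 of them in the total WT libraries labelled with that line.

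Genes with a slower relative loss in KO differed in sequence from other genes across protein-coding genes, which are not independent replicates. Low GC at the last position of codons, a candidate explanation, had a Spearman rho with the slope difference of -0.156 (-0.301 in the 3563 genes of highest expression), and AU content of the 3' UTR one of 0.195 (0.287 in the 3472 of highest expression). Long 3' UTRs were argued against, with a rho of 0.0267 over all and 0.0894 in the 3524 of highest expression. With the slope in WT itself, GC at this position had a rho of 0.0655 (0.288 at high expression), AU content of the 3' UTR one of -0.138 (-0.206) and 3' UTR length one of -0.282. AU-rich transcripts were thus lost faster in WT, as were those of low GC at the last codon position, mainly at high expression. The rho of 0.195 for AU content and that of -0.301 for GC may therefore in part restate the narrower range of slopes in KO. A narrower range alone would leave each rho with the slope in KO as in WT. In KO it was -0.0446 (-0.078 at high expression) for AU content and -0.00695 (0.197) for GC. For 3' UTR length it was -0.329 in KO, against 0.0267 with the slope difference. These values argue against the narrower range as the whole explanation.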
